A study of Homo sapiens with 9 samples.

How the data were processed

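The series holds 9 DNA:RNA immunoprecipitation (DRIP-seq) libraries from U2OS, a human osteosarcoma cell line. R-loops, in which RNA pairs with 1 DNA strand and leaves the other unpaired, were captured from genomic DNA with S9.6, an antibody that binds DNA:RNA hybrids. Per the labels' protocols, the DNA was cut with restriction enzymes before the precipitation, then sonicated and ligated to Illumina adapters. Of the libraries, 6 were untreated with RNase H: 2 from control cells, 2 from cells given FG and 2 from cells given PDS (pyridostatin). Both compounds bind G-quadruplexes, 4-stranded structures formed by guanine-rich DNA. The other 3 libraries, 1 per condition, were treated with RNase H, which degrades the RNA of DNA:RNA hybrids. Groups and replicate numbers were taken from the sample titles. Dose and treatment time were not given in the sources used here.

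Per the submitters' processing notes, the tools were Trimmomatic 0.35, BWA 0.7.12, SAMtools 1.3.1 and MACS2 2.1.1.20160309, and the genome build was hg19. Their settings, any filter on duplicate or multiply mapped reads, and any input library used in peak calling were not given in the sources used here. Each library had 1 deposited peak list of 10 columns without a header, in the layout of MACS2, so peaks were called per library and not on pooled replicates. Each list gave for every peak its position, the deposited length in bp, the pileup (a coverage signal) at the summit, the −log10 of the p-value, the fold enrichment over the local background and the −log10 of the q-value. These column meanings were read from the deposited values, since lengths equalled end minus start plus 1 and the remaining columns followed the caller's usual order. The smallest deposited −log10 q in the 6 main lists was 1.30, equivalent to a q-value of 0.05. Peak names carried numbers, and the highest number exceeded the count of listed peaks by 296 to 487 in the 6 main lists, so some called peaks were not analysed here. The deposited fold and q-values are each peak's own and served only to rank or filter peaks within a list.

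Read totals were not given in the sources used here. A relative depth was therefore estimated from the lists. The background pileup under a peak follows from its pileup and fold, and its minimum in each list, at which 29.3 to 34.9% of peaks sat, was divided by the shortest peak length as a stand-in for fragment length. This estimate, relative to control 1, was 0.821 in control 2, 1.03 in FG 1, 1.05 in FG 2, 1.01 in PDS 1 and 1.09 in PDS 2. The ratios depend on the shortest peak length, since the background pileup alone, relative to control 1, was 0.957 in control 2, 1.24 in FG 1, 1.19 in FG 2, 1.18 in PDS 1 and 1.17 in PDS 2. Neither estimate gives a counting interval for a single peak.

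All further values were computed from the peak positions with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Covered length is the union of a library's peaks. For each contrast (FG against control, PDS against control, FG against PDS), overlapping peaks of the 4 libraries (at least 1 bp) were merged into regions. A region was gained if peaks of both libraries of the first group and of neither library of the second lay in it, and lost in the reverse case. The same counts were made for every other choice of 2 of the 4 libraries. The bases covered in both ligand libraries and in neither control library were set against control peaks within 1 kb, with 100 random placements outside control peaks on the same chromosomes as a reference. The overlap of regions gained with FG and with PDS used regions merged over all 6 libraries, and was compared with 100 simulations of unchanged groups against the same controls. Library values were compared by exact two-sided permutation tests, whose smallest possible p with 2 libraries against 2 is 0.333. Peak numbers after RNase H were compared with the untreated lists by an exact permutation within conditions, added after the lists were seen.

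No genome or annotation of hg19 was used here, and the gene table at hand names another build (GRCh38), so regions were not assigned to genes. In place of genes, the genome was divided into 100 kb windows, and log2(covered kb + 0.5) was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend and robust). All 6 libraries entered 1 fit with 3 residual degrees of freedom. Windows needed at least 0.5 kb of cover in 2 libraries, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes on this scale understate changes in windows with little cover. The covered share of each chromosome was fitted in the same way on the log2 scale. The planned tests of gene lists, of position relative to genes and of G-quadruplex motifs needed that annotation or sequence and were not run.

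Named regions followed a rule set before the data were examined: the 5 widest gained and 3 widest lost regions per contrast, and every peak of the RNase H lists. Named windows were the 5 highest and 3 lowest per contrast, filled by smallest p among windows with the same direction in all 4 pairs of libraries where none passed the threshold. Alternatives covered a −log10 q of at least 5, an equal number of peaks per list (45702, the strongest by deposited −log10 p), other merging and overlap rules, other pseudocounts, filters, scales and models, the replicate number as a block and leaving out each library in turn.

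Region counting was tested on simulated lists with 4000 sites, where all 13 planted quantities were recovered. The window fit was tested on the 11884 windows for PDS against control with 200 planted changes. With each window's own spread, 0% of changes of log2 1, 1.49% of log2 2 and 9.09% of log2 4 were recovered. With 0.25 of that spread, 38.8%, 82.1% and 100% were recovered, with 4 false calls. Nothing in the labels says whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.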

Results

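DRIP-seq peak lists from U2OS cells were compared to ask how the R-loop map differed after exposure to the G-quadruplex ligands FG and PDS. The 6 libraries without RNase H held between 45702 and 94277 peaks. Control 1 had 56393 peaks over 109.7 Mb and control 2 had 45702 over 53.6 Mb. The FG libraries had 56092 peaks over 130.4 Mb and 75625 over 170.4 Mb, and the PDS libraries had 62937 over 124.9 Mb and 94277 over 196.5 Mb. Median peak width was 868 and 639 bp in the controls, 1081 and 1085 bp with FG, and 1050 and 984 bp with PDS. Estimated depth lay between 0.821 (control 2) and 1.09 (PDS 2) of that of control 1.

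Few peaks were listed after RNase H treatment. The lists of the RNase H-treated control, FG and PDS libraries held 4, 16 and 3 peaks, covering 1.93, 7.21 and 1.07 kb, which is at most 0.0285% of the peak number of the shorter matched list. With 1 such library per condition, the conditions could not be compared with each other. Over the conditions together, the treated lists held 65163 fewer peaks than the untreated lists of their condition. The exact permutation p was 0.0370 over the 27 ways to take 1 library per condition as treated, the smallest these ways allow. That test was chosen after the lists were seen. Depth was not estimated for the treated lists, so lower depth cannot be told apart from a loss of hybrids. Only 1 site occurred in all 3 lists, on chromosome X from 118570760 to 118571271 (hg19), and peaks of 5 of the 6 untreated libraries, all but FG 1, overlapped it. A site on chromosome 14 from 31158779 to 31159182 was listed in the control and PDS libraries with RNase H and in none of the 6 untreated lists. In the control list the other 2 peaks lay on chromosome 16 from 84044764 to 84045430 and on chromosome 3 from 185228657 to 185229032, and in the PDS list the other lay on chromosome 9 from 38977042 to 38977397, and none of these 3 overlapped an untreated peak. Of the 16 peaks in the FG list, 5 overlapped a peak of an FG library without RNase H: on chromosome 13 from 113922294 to 113922669, chromosome 17 from 19557060 to 19557497, chromosome 5 from 69790767 to 69791157, chromosome 8 from 26256128 to 26256726, and the chromosome X site. The remaining 11 overlapped no untreated peak. They lay on chromosome 11 from 48172119 to 48172529, chromosome 16 from 46477305 to 46477678, chromosome 18 from 459319 to 459691 and from 77410027 to 77410423, chromosome 2 from 71640978 to 71641545, chromosome 21 from 11036142 to 11036940, chromosome 6 from 25900840 to 25901228, chromosome 7 from 30967877 to 30968263 and from 68157447 to 68157823, chromosome 8 from 66266195 to 66266587, and chromosome 9 from 66500480 to 66500909.

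Peaks covered more of the genome in each ligand library than in either control library. The mean was 81.6 ± 39.7 Mb in control cells, 150.4 ± 28.3 Mb with FG and 160.7 ± 50.6 Mb with PDS (SD, n = 2 each). This was 1.84 times the control length with FG (log2 ratio 0.88, SE 0.55) and 1.97 times with PDS (log2 ratio 0.98, SE 0.61), and the exact two-sided permutation p was 0.333 for both, the smallest that 2 against 2 allows. Median peak width was 754 ± 162 bp in controls, 1083 ± 2.83 bp with FG and 1017 ± 46.7 bp with PDS (SD, n = 2 each), with log2 ratios of 0.52 (SE 0.22) and 0.43 (SE 0.23) and an exact p of 0.333 for each. Peak number did not separate the FG libraries from the controls (log2 ratio 0.37, SE 0.26, exact p = 0.667), while both PDS libraries had more peaks than both controls (log2 ratio 0.62, SE 0.33, exact p = 0.333). Without control 2, the log2 ratio of covered length was 0.46 for FG and 0.55 for PDS, and without control 1 it was 1.49 and 1.58. Covered length followed estimated depth over the 6 libraries (Pearson r = 0.93, permutation p = 0.00139; Spearman rho = 1, permutation p = 0.00278; both 0.00556 after adjustment over 4 relations), and r was 0.94 without control 2 and PDS 2, the libraries farthest from the median depth. With the background pileup alone as the estimate of depth, the relation was weaker (r = 0.73, permutation p = 0.110, adjusted p = 0.146; rho = 0.60, permutation and adjusted p = 0.242), and r was -0.48 among the 4 ligand libraries, since the controls were then farthest from the median. These relations were chosen after the lists were seen.

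**Figure D1:**
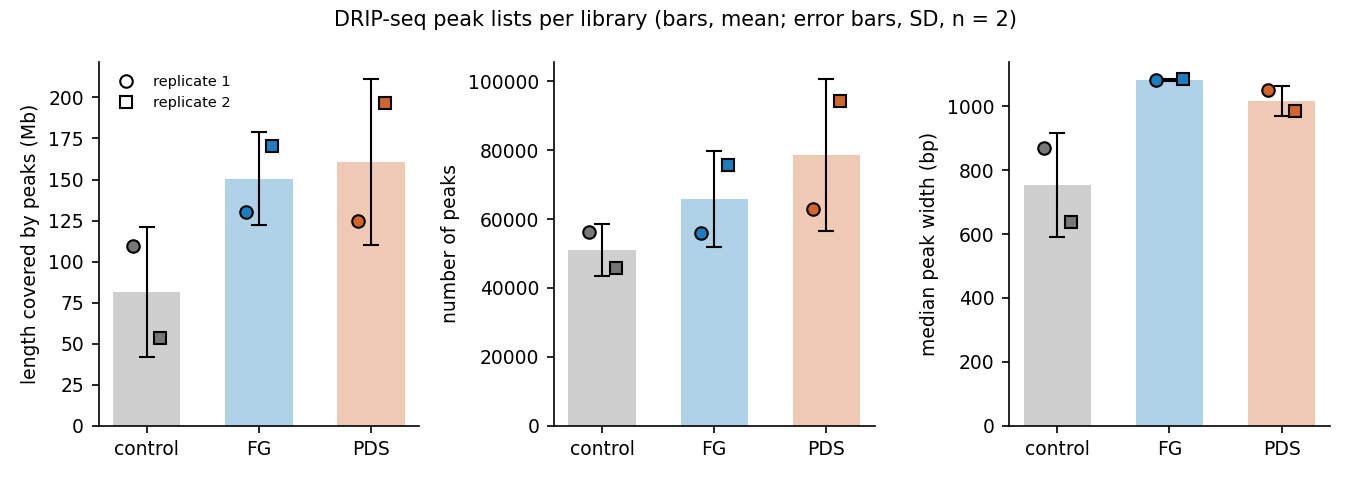
Covered length in Mb, number of peaks and median peak width in bp for the 6 DRIP-seq libraries without RNase H; bars are group means, error bars are SD (n = 2) and points are libraries. Covered length was 53.6 and 109.7 Mb in the controls and 124.9 to 196.5 Mb in the 4 ligand libraries.

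With FG, 7944 regions were gained and 301 were lost among 95069 merged regions, 26.4 times as many gained as lost, and 14282 regions were present in all 4 libraries. The widest gained region, on chromosome 10 from 121426373 to 121435028, spanned 8656 bp, with 4.12 kb covered in FG 1 and 8.66 kb in FG 2 and none in either control. The next widest were on chromosome 10 from 70487945 to 70495957 (8013 bp) and from 122664326 to 122672178 (7853 bp), and on chromosome 1 from 16727769 to 16735240 (7472 bp) and from 52486872 to 52494182 (7311 bp). Their width came mostly from FG 2, which covered 6.95 to 8.01 kb of them, while FG 1 covered 0.464 to 3.34 kb. The widest lost regions were on chromosome 19 from 39960633 to 39969814, chromosome 10 from 77155420 to 77164404 and chromosome 22 from 42533989 to 42541823. At the chromosome 22 site peaks covered 7.84 kb in control 1 and 5.58 kb in control 2. Gained regions had a median width of 1355 bp and lost regions of 786 bp. Other ways to take 2 of these 4 libraries gave between 214 and 3484 regions present in those 2 and absent from the rest, all fewer than 7944. Both FG libraries had longer cover than either control, so their pair can have the most regions through list length alone. This comparison is therefore no test of a gain. With a deposited −log10 q of at least 5 in both FG libraries and no control peak, 1278 gained regions (16.1%) and, by the mirrored rule, 49 lost regions were left. An equal number of peaks per list gave 4480 gained and 412 lost regions, but covered length over control still had a log2 ratio of 0.78. The counts depended on requiring 2 libraries per group: 37151 regions were gained and 549 lost without FG 1, 18570 and 1058 without FG 2, 21306 and 12131 without control 1, and 8988 and 5666 without control 2. The excess of gained over lost regions was thus much smaller with a single control, where a lost region needs a peak in that control alone and a gained region still needs peaks in both FG libraries.

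With all peaks and both controls, most of the FG-gained sequence lay close to sites already listed in control cells. Of 23.4 Mb covered in both FG libraries and in neither control, 65.0% lay within 1 kb of a control peak, against 2.48% (range 2.32 to 2.65%) over 100 random placements. Merged regions that also held a control peak contained 75.5% of the gained sequence. A ligand peak wider than a control peak leaves gained sequence beside that control peak by construction. The placements were spread over whole chromosomes outside control peaks, so they are no test. Sequence lost with FG came to 0.531 Mb, of which 74.5% lay within 1 kb of an FG peak. In the regions present in all 4 libraries, the median length covered was 3392 bp (control 1), 1346 bp (control 2), 3758 bp (FG 1) and 4316 bp (FG 2). Taken region by region, the median log2 ratio to control 1 was 0.04 (FG 1), 0.15 (FG 2) and -0.92 (control 2). Both FG libraries were thus only slightly longer than control 1 at these sites. Without control 1 the share within 1 kb was 36.3%, with FG 2 alone 43.7%, and with only peaks at a −log10 q of at least 5 it was 44.6%. It was 61.5% without control 2 and 59.6% with FG 1 alone.

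The window carrying the smallest p for FG against control was on chromosome 10 from 122600001 to 122700000, with 6.80 and 13.3 kb covered in FG 1 and FG 2 and 0 kb in both controls (log2 change 4.32, SE 0.92). Its log2 change was 6.58 with a pseudocount of 0.1 kb and 3.40 with 1 kb. Sizes of change in windows without cover in a group thus depend on the pseudocount. Windows on chromosome 14 from 23900001 and from 93400001, chromosome 1 from 183000001 and chromosome X from 153800001 followed, with log2 changes of 3.97, 3.86, 3.70 and 3.48. In the other direction, the window on chromosome 16 from 900001 to 1000000 had 3.61 and 3.76 kb in the controls against 0.429 and 0 kb with FG (log2 change -2.62, SE 0.91), and windows on chromosome 1 from 228700001 and chromosome 8 from 102400001 had log2 changes of -2.80 and -2.52. None of the 11884 windows passed the threshold in limma (smallest adjusted p = 0.328), and at an unadjusted p under 0.05 there were 1776 higher and 3 lower. With the replicate number as a block, 2 passed. Cover was higher in all 4 pairs of an FG and a control library in 7078 windows (59.6%) and lower in all 4 in 89 (0.749%), where chance gives 16.7% each way for a single window. The windows share the same libraries and each ligand library had more total cover than either control, so this tally is no test, and after dividing by total cover the numbers were 2992 (25.2%) and 1734 (14.6%). The median log2 change over windows was 1.04, and dividing by each library's total cover brought it to 0.29, with 644 higher and 88 lower windows at an unadjusted p under 0.05. Without control 1, 2053 windows passed, and without any other single library, 0.

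With PDS, 9748 regions were gained and 364 were lost among 115770 merged regions, and 14170 were present in all 4 libraries. The widest gained region, on chromosome 9 from 100424954 to 100447683, spanned 22730 bp, with 4.30 kb covered in PDS 1 and 22.7 kb in PDS 2. The next widest lay on chromosome 1 from 54225861 to 54243676 (17816 bp), chromosome 2 from 182774524 to 182791998 (17475 bp), chromosome 1 from 185254774 to 185269733 (14960 bp) and chromosome 6 from 144173263 to 144187953 (14691 bp). In all 5, PDS 2 was covered over the full width and PDS 1 over 1.21 to 5.21 kb. The widest lost regions were on chromosome 20 from 30946728 to 30952697, chromosome 19 from 39952664 to 39956557 and chromosome 1 from 43209068 to 43212761. Gained regions had a median width of 1553 bp and lost regions of 782 bp. Other choices of 2 of the 4 libraries gave 299 to 3670 regions, which is again no test, since both PDS libraries had longer cover than either control. With a −log10 q of at least 5 in both PDS libraries and no control peak, 2769 gained regions (28.4%) were left, against 55 lost by the mirrored rule. An equal number of peaks per list gave 4334 gained and 683 lost regions, again with a log2 ratio of covered length over control of 0.78. Without PDS 1 there were 54364 gained and 828 lost regions, and without PDS 2 23504 and 1347. With a single control the excess of gained over lost was again much smaller, with 21800 and 11283 without control 1 and 11069 and 7080 without control 2.

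Much of the PDS-gained sequence also lay near control peaks. Of 23.2 Mb gained with PDS, 52.1% lay within 1 kb of a control peak, against 2.17% (range 1.98 to 2.38%) over 100 random placements, which are no test here either. Merged regions with a control peak contained 65.2% of the gained sequence. Of the 0.848 Mb lost, 81.5% lay within 1 kb of a PDS peak. Median covered length in the common regions was 3466 bp (control 1), 1391 bp (control 2), 3563 bp (PDS 1) and 4692 bp (PDS 2). Taken region by region, the median log2 ratio to control 1 was -0.02 (PDS 1), 0.14 (PDS 2) and -0.92 (control 2). The share within 1 kb was 36.2% without control 1, where it was nearly that of FG. It was lower than that of FG without control 2 (48.0% against 61.5%) and with an equal number of peaks per list (51.4% against 62.2%). With only peaks at a −log10 q of at least 5 it was also lower (34.4% against 44.6%). Without FG 1 it was higher (52.1% against 43.7%). The order of the ligands thus depended on the libraries used and was not tested. The share was 31.3% with PDS 2 alone and 48.3% with PDS 1 alone.

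Some windows named for PDS against control were also named for FG, which the shared controls alone can produce, and this agreement was not tested. On chromosome 1 from 183000001 to 183100000, PDS 1 and PDS 2 had 14.0 and 22.2 kb against 0.515 and 0 kb in the controls (log2 change 4.67, SE 0.89). The chromosome 10 window from 122600001 had 7.03 and 19.7 kb against 0 kb (log2 change 4.62, SE 0.92, and 6.89 or 3.69 with a pseudocount of 0.1 or 1 kb). Windows on chromosome 4 from 22400001, chromosome 2 from 112900001 and chromosome 6 from 97700001 had log2 changes of 4.36, 4.10 and 4.09. The chromosome 16 window from 900001 had the smallest p among lower windows, with no cover in either PDS library (log2 change -3.06, SE 0.91), and windows on chromosome 9 from 68300001 and chromosome 1 from 161400001 had log2 changes of -2.33 and -2.01. No window passed the threshold in limma (smallest adjusted p = 0.180), and 2745 were higher and 4 lower at an unadjusted p under 0.05. This depended on the model, since 472 higher and 1 lower window passed with the replicate number as a block. The labels do not say that equal numbers are pairs. Cover was higher in all 4 pairs of libraries in 6508 windows (54.8%) and lower in 90 (0.757%), with 16.7% each way by chance for a single window, and after dividing by total cover in 3497 (29.4%) and 1753 (14.8%). The median log2 change was 1.21, and 0.42 after dividing by total cover, with 1256 higher and 405 lower windows at an unadjusted p under 0.05. Without control 1, 1820 windows passed, without PDS 1, 478, and without any other single library, 0.

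By chromosome, the share covered by peaks was higher on each of chromosomes 1 to 22 and X in the fit with either ligand, and mostly by less on densely covered chromosomes than on sparsely covered ones. On chromosome 19, peaks covered 19.02% and 8.82% in the controls, 20.4% and 22.6% with FG, and 17.7% and 21.01% with PDS (log2 change 0.73, SE 0.57, for FG and 0.58, SE 0.57, for PDS). On chromosome 4 they covered 1.31% and 0.650% in the controls, 1.65% and 2.48% with FG, and 1.77% and 3.36% with PDS (log2 change 1.13, SE 0.75, and 1.40, SE 0.75). Chromosome 13 had log2 changes of 1.41 and 1.67, chromosome 18 of 1.13 and 1.33, and chromosome 22 of 0.88 and 0.75. The order was not strict, since the sparsely covered chromosome X had 1.04 and 1.10 and chromosome 6 had 0.90 and 1.09, below the more densely covered chromosome 14 with 1.11 and 1.23. After dividing by total cover the direction differed between chromosomes. The log2 changes were -0.23 (FG) and -0.46 (PDS) on chromosome 19 (SE 0.17 each) and 0.17 and 0.37 on chromosome 4 (SE 0.12 each). No chromosome passed the threshold in limma after this division (smallest adjusted p = 0.571 for FG and 0.102 for PDS). At an unadjusted p under 0.05 there were then 1 higher for FG, and 6 higher and 2 lower for PDS. Without the division no chromosome passed either (limma, smallest adjusted p = 0.201 for FG and 0.180 for PDS), and at an unadjusted p under 0.05 there was 1 for PDS and 0 for FG. Without control 1, 17 chromosomes passed for FG and 22 for PDS, and without control 2, 0 did.

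**Figure D2:**
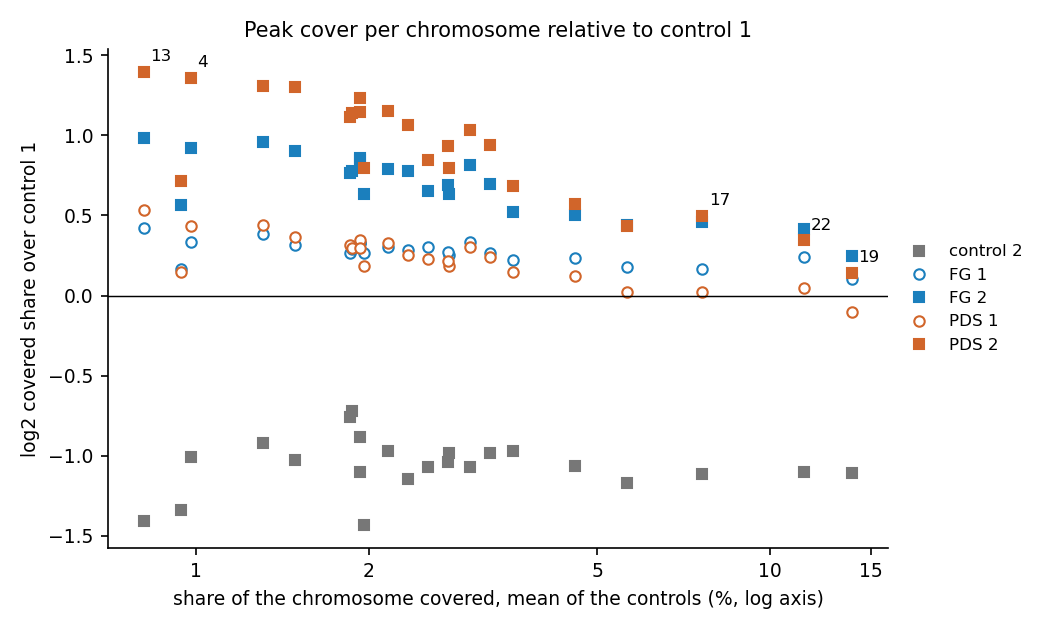
Log2 ratio of the covered share over that of control 1 (vertical axis) against the mean covered share of the 2 controls in percent (horizontal log axis), 1 point per chromosome and library, chromosomes 1 to 22 and X. In PDS 2 the log2 ratio was 1.40 on chromosome 13 and 0.14 on chromosome 19, and in control 2 it was below 0 on every chromosome drawn.

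FG and PDS were compared directly, without dose or time, which the labels do not give. The FG libraries had 1895 regions absent from both PDS libraries, and the PDS libraries had 2559 absent from both FG libraries, among 107186. The 5 widest regions of FG only were on chromosome 10 from 43926299 to 43931042 and from 43702471 to 43706925, chromosome 18 from 43675156 to 43679690, chromosome 16 from 32349395 to 32353895 and chromosome 1 from 3569753 to 3573985. The widest region of PDS only, on chromosome 22 from 42534041 to 42542915, overlapped the control region lost with FG, and was covered over 7.87 kb in PDS 1 and 1.01 kb in PDS 2. Chromosome 12 from 52590428 to 52598256 and chromosome 4 from 79842093 to 79848691 followed. There PDS 2 covered 7.83 and 6.60 kb, and PDS 1 only 0.716 and 0.709 kb. These counts were below that of a choice of libraries across the ligands, since 10435 regions were present in FG 2 and PDS 2 and absent from FG 1 and PDS 1. Leaving out FG 1, FG 2, PDS 1 or PDS 2 gave 12469, 7354, 4605 or 6137 regions of FG only and 3397, 8008, 33193 or 9537 of PDS only. Which ligand had more regions of its own also turned with an equal number of peaks per list (1734 of FG only, 1409 of PDS only) and when presence required 50% of the region to be covered (2544 and 2526).

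Covered length with FG over PDS had a log2 ratio of -0.10 (SE 0.38, exact p = 1), peak number of -0.26 (SE 0.36, exact p = 0.667) and median width of 0.09 (SE 0.05, exact p = 0.333). The ratio of covered length changed sign with the library left out, from -0.39 without PDS 1 to 0.27 without PDS 2. The window on chromosome 21 from 45900001 to 46000000 had 3.27 and 3.31 kb with FG and 0 kb in both PDS libraries (log2 difference 2.92, SE 0.93), followed by windows on chromosome 1 from 228100001 and from 166900001, chromosome 16 from 85300001 and chromosome 6 from 99200001 (2.66, 2.58, 2.62 and 2.54). On chromosome 6 from 57300001 to 57400000, PDS had 4.64 and 3.93 kb and FG 0 kb (log2 difference -3.26, SE 0.89), and windows on chromosome 12 from 101000001 and chromosome 7 from 124500001 had -3.10 and -3.18. None of the 11884 windows passed the threshold in limma (smallest adjusted p = 1), with 20 higher and 107 lower at an unadjusted p under 0.05. No chromosome passed either (smallest adjusted p = 0.969, with 0 at an unadjusted p under 0.05).

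**Figure D3:**
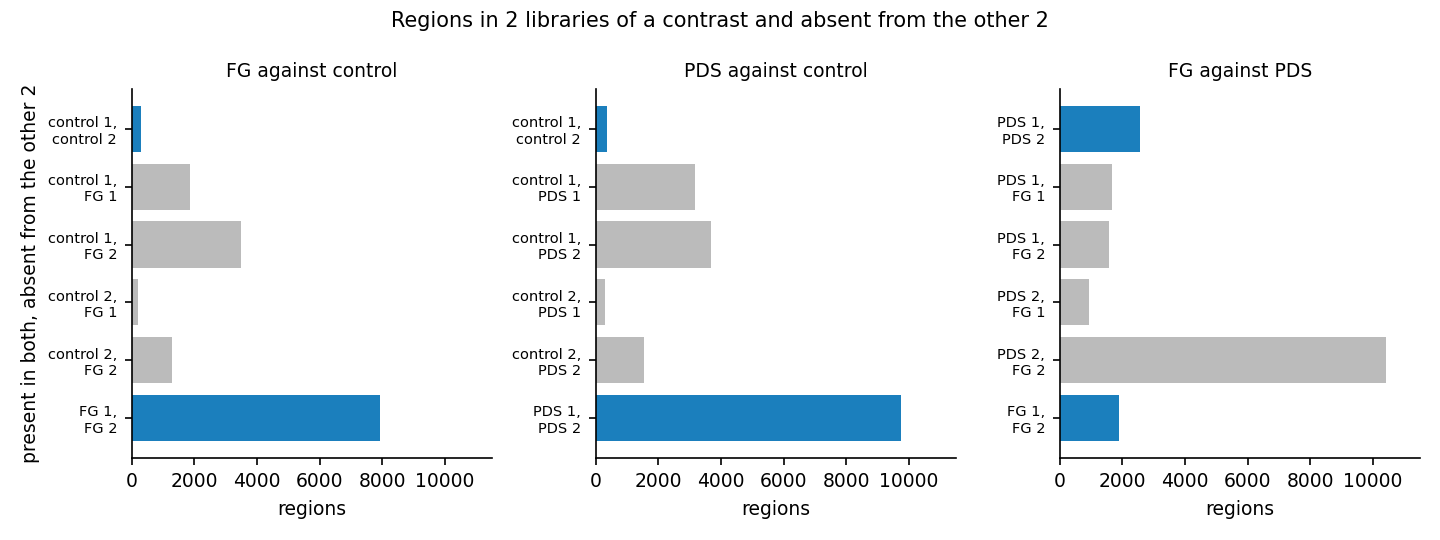
Number of regions (horizontal axis) present in the 2 libraries named and absent from the other 2 of each contrast; blue bars are pairs from 1 group and grey bars pairs across groups. For FG and PDS against control the pair of ligand libraries had the most regions (7944 and 9748), and for FG against PDS the pair FG 2 and PDS 2 did (10435). In each contrast these were the 2 libraries with the longest covered length.

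Regions gained with both ligands were counted over all 6 libraries. Among 118819 regions, 6739 were gained with FG and 8938 with PDS, and 3069 with both, which is 45.5% of the FG-gained and 34.3% of the PDS-gained regions. Independent lists of these sizes would share 507, and simulated unchanged groups against the same controls shared a mean of 1696 (range 1611 to 1793). These simulations kept each ligand library's number of regions and took the rate of each region from all 6 libraries. In them a mean of 6550 regions were gained with FG and 10802 with PDS, against 6739 and 8938 observed. Because the rates include the ligand libraries, regions gained in those tend to be gained again in the simulations. The simulated counts therefore cannot show whether the gain exceeds that of unchanged groups. The controls numbered only 2 and were not split, so part of the excess of shared regions may come from the shared controls. Likeness between single ligand libraries, such as FG 2 and PDS 2, may also contribute, and neither was tested. A peak of at least 1 PDS library lay in 82.9% of the FG-gained regions, and a peak of at least 1 FG library in 75.5% of the PDS-gained ones. Only 131 regions were present in both controls and absent from all 4 ligand libraries, and 13288 were present in all 6. Without control 1 the number gained with both ligands was 11837, without FG 1 6490 and without PDS 1 4865.

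Libraries of 1 group shared little more peak area than libraries of different groups. The Jaccard index, the shared over the combined covered length, averaged 0.468 within groups and 0.453 between groups, and 5 of the 15 ways to pair the 6 libraries reached the within-group mean (exact p = 0.333). The highest index was 0.636, between control 1 and FG 1. FG 1 and FG 2 had 0.606, PDS 1 and PDS 2 0.461, and control 1 and control 2 0.338. Control 2 had indices of 0.214 to 0.338 with the other libraries. The best pairing put control 1 with control 2, FG 1 with PDS 1 and FG 2 with PDS 2 (mean 0.516).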

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

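The alternative that asked for strong peaks only where a region was present, the rescaled chromosome fit without control 2, and the test of RNase H with its alternatives were chosen after the data were seen. So was the relation of covered length to estimated depth, also with the background pileup alone. With 2 libraries per group the exact tests between groups cannot pass a threshold, so directions and counts are compared here, and the cause of a change was not tested unless stated. Covered length, peak number and median width kept their direction for FG and for PDS against control under every alternative run. Each ligand library exceeded both controls in covered length and median width. Leaving out a library or adding the block therefore could not turn the direction of these measures. Of 383 recomputed values of named windows, none changed sign. These windows had been picked for the same direction in every pair of libraries. Leaving out a library, another pseudocount, the block or other eBayes options therefore could not turn their sign. The unchanged signs are thus no test of the named windows. Of 72 recomputed values for named regions, 67 moved by no more than the replicate spread, the larger SD of the groups, and 5 by more. Leaving out chromosome Y could not move any of them, since no named region lies on it. The spread was wide where a single library covered most of a region. These values are therefore no test of the named regions either.

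Only peaks at a −log10 q of at least 5 gave 4188 gained and 124 lost regions with FG, 5975 and 158 with PDS, 863 and 1459 for FG against PDS, and 1924 gained with both. The share of gained sequence within 1 kb of a control peak was then 44.6% (FG) and 34.4% (PDS). With all peaks, the share within 5 kb was 89.3% and 79.3%, against 12.4% and 11.6% over random placements, a reference that is again no test. An equal number of peaks per list gave 4480 gained with FG, 4334 gained and 683 lost with PDS, 1734 of FG only against 1409 of PDS only and 1429 gained with both, and turned the log2 ratio of median width of FG over PDS to -0.13. Requiring 50% of a region to be covered gave 2544 of FG only and 2526 of PDS only, so both of these alternatives turned the order of the 2 ligands. Merging peaks within 1 kb gave 5276 gained and 181 lost (FG), 209 lost (PDS) and 1010 of FG only. Strong peaks where present and no peak where absent gave 1278 and 49 (FG), 2769 and 55 (PDS), and 135 and 377 (FG against PDS). Without the filter on low cover, 3 (FG) and 94 (PDS) windows passed. With all libraries, no chromosome passed for either ligand after dividing by total cover. Dividing by total cover without control 2, 1 chromosome passed for PDS. The rank correlation of covered length with depth went from 1 to 0.60 (permutation p = 0.242) with the background pileup alone.

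Leaving out 1 library gave 7944 to 37151 gained and 301 to 12131 lost regions (FG), 9748 to 54364 and 364 to 11283 (PDS), 1895 to 12469 and 2559 to 33193 (FG against PDS), and 3674 to 11837 gained with both; asking 1 library in place of 2 raises these counts by construction. The share within 1 kb was 36.3 to 65.0% (FG) and 31.3 to 52.1% (PDS). Peak numbers after RNase H minus those of the untreated lists averaged -70386.7 to -59940 when 1 untreated library was left out, with an exact permutation p of 0.0556, the smallest that 18 assignments allow, against 0.0370 for all libraries and for peaks at a −log10 q of at least 5 (-35083.8). The log2 ratio of FG over PDS was -0.39 to 0.27 for covered length and -0.52 to 0.065 for peak number. Windows passing were 0 to 2053 (FG) and 0 to 1820 (PDS), and chromosomes 0 to 17 and 0 to 22; the high ends came without control 1, which leaves 1 control with the shortest covered length and the spread of the other groups.

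With the replicate number as a block, 2 windows passed for FG and 473 for PDS (472 higher and 1 lower), and 0 for FG against PDS; no chromosome passed. The blocked log2 ratio of covered length was 0.96 (FG), 1.03 (PDS) and -0.07 (FG over PDS). Deviations of same-numbered libraries from their group means correlated at 0.27 (control and FG), 0.25 (control and PDS) and 0.59 (FG and PDS) over windows, but with 2 numbers this does not establish pairs. Gene lists, positions relative to genes, motif and GC counts and the gene flank were not run for lack of an hg19 annotation.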

Other observations

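Of the tests in this part, 2 were fixed before their result was seen: the share of strong regions among those of FG 2 and PDS 2, and the comparison of windows with similar control 2 cover. The others were chosen after the values they use were seen.

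The longer cover in the ligand libraries followed estimated depth exactly in rank (Spearman rho = 1 over 6 libraries), but the background pileup not divided by peak length gave a rho of 0.60, so depth may account for part of it. Among control 1, FG 1 and FG 2, 1599 regions with a −log10 q of at least 5 in both FG libraries had no peak in control 1, 661 strong in control 1 and FG 2 had none in FG 1, a ratio of 2.42 (95% counting interval 2.21 to 2.65), and 260 strong in control 1 and FG 1 had none in FG 2, a ratio of 2.54 between the FG libraries themselves. Among control 1, PDS 1 and PDS 2 these numbers were 3411, 785 and 753, with ratios of 4.35 (4.02 to 4.70) and 1.04, but the background pileup of PDS 1 was 1.18 times that of control 1. Depth, precipitation yield, a difference between single libraries and an effect of the ligands therefore cannot be told apart. An equal number of peaks per list lowers but does not end the excess of gained regions (4480 with FG, 4334 with PDS). It did not equalise cover, since the log2 ratio of covered length over control was still 0.78 with each ligand. Simulated groups with the same list lengths gained 6550 and 10802 regions over all 6 libraries, against 6739 and 8938 observed. Their rates came partly from the ligand libraries, so these counts decide nothing here.

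FG 2 and PDS 2 shared 10435 regions absent from FG 1 and PDS 1, more than either ligand's 2 libraries shared against the other. Of these regions, 22.4% (2333) had a −log10 q of at least 5 in both FG 2 and PDS 2, above the share set beforehand as arguing against depth. That rule assumed correct depth estimates, and the 2 estimates differ. FG 2 and PDS 2 also had the longest cover, so this share cannot exclude depth. Of the 1659 regions of FG 1 and PDS 1 only, 13.3% (220) were strong in both, which also exceeds the share set beforehand. Deviations of same-numbered FG and PDS libraries correlated at 0.592 over windows, which with 2 libraries per group restates the sharing, so it decides nothing about a difference that follows the replicate number, such as a shared preparation. The labels name no batch, no biological explanation was tested, and the cause stays open.

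Ligand cover was shifted toward sparsely covered chromosomes. Over 23 chromosomes, the slope of the log2 ratio to control 1 on log2 control cover was -0.05 (FG 1), -0.15 (FG 2), -0.12 (PDS 1) and -0.28 (PDS 2), and 0.01 (SE 0.04) for control 2. The shallowest of the 4, -0.0478, is smaller in size than the slopes of -0.10 and -0.16 of FG 2 over FG 1 and of PDS 2 over PDS 1, while that of control 1 over control 2 was -0.00742, so a ligand effect and a depth or library effect cannot be told apart with 2 libraries per group. In windows with 2 to 10 kb of control 2 cover, 59.4% of the mean difference of the 4 ligand libraries between the 5 least and 5 most covered chromosomes was left, a ratio that weighs libraries with a large difference most. This is above the share set beforehand as arguing against limited room in densely covered windows. By library the share was 37.4% (FG 1), 51.3% (FG 2), 64.1% (PDS 1) and 65.6% (PDS 2), and FG 1 was below the share set beforehand. Control 2 cover still varied within these windows, and control 1 cover was not matched. The comparison therefore does not decide, and limited room may explain part of the shift.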
